A study of Mus musculus with 6 samples.

How the data were processed

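RNA sequencing was done on 6 libraries of mouse cultures labelled as female germline stem cells, 3 treated with DMSO and 3 with C89, at 8 h. Per the labels' protocol, RNA was extracted with Trizol and mRNA libraries were sequenced from both ends; the protocol names library kits of 2 makers without saying which step used which. HISAT2 and DESeq2 are named in the submitters' processing notes, without versions. The genome build, annotation and counting tool are not given in the sources used here, so no coordinates are printed. How reads of overlapping or antisense genes were assigned is likewise not stated.

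The authors deposited 1 table of 54232 genes. Per the file headers it holds a mean, a log2 fold change, an adjusted p-value and a value per library. The deposited value per library is a signal of read counts divided by 1 size factor per library, as its steps show: each of 119023 values above 0 was a whole number of reads within 0.01 read (100%). The log2 fold changes and adjusted p-values in the deposited table are the authors' own and carry DESeq2's column names per the file headers. Read counts were recovered by dividing each deposited value by its library's step. Recovered totals were 21763459, 17849625 and 17826569 reads in DMSO and 17938295, 7772060 and 12479644 reads in C89 libraries, so that 1 read is worth 0.667 to 2.032 normalized counts. Depth limits genes of a few reads most in the second C89 library. Floors for genes without reads use 3 reads over a group and cover counting error only, since the reads carry no molecular identifiers here.

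One gene was left out because a cell held text, which left 54231. Symbols were taken from a reference table by Ensembl identifier, because 27 symbols had been stored as dates; 54079 identifiers matched and 153 did not. Of 24129 symbols given in both places, 23342 were equal. A further 6 unnamed columns held a copy of values of Mtor and were not used.

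The planned test for raw counts was replaced by its planned fallback because the deposited values were normalized: limma 3.58.1 with a mean-variance trend (R 4.3.3) on log2(value + 1), for 18954 genes with a mean of at least 1 over the 6 libraries, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Count tests on the recovered reads were alternatives, with edgeR 4.0.16 (4928 genes called) and DESeq2 1.42.0 (4480 genes). Fold changes on this scale understate the change of low genes. Before the data were examined, 37 gene lists were fixed. The 35 with at least 3 tested members, a minimum set after the members were counted, were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Other choices made before the data were examined were the design, the rule for named genes and most of the other settings tried.

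The named genes were those with the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 normalized counts whose groups did not overlap, leaving out predicted genes, pseudogenes and identifiers without a symbol. To these were added the 5 called genes with the lowest p in each direction under the same filters, the 3 tested members with the lowest p of each list, and a fixed set: Map1lc3a, Map1lc3b, Sqstm1, Becn1, Ulk1, Atg5, Atg7, Akt1, Mtor, Pik3ca, Ddx4, Dazl, Ifitm3, Pou5f1, Col1a1 and a further gene that is not reported here. Genes named outside this rule, such as Piwil2 and those of the added blood cell lists, were chosen after values had been seen.

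The procedure was tested on simulated data, drawn for C89 against DMSO from the real means and library sizes over 19013 genes. limma recovered 70.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 6 false calls among 185. The simulation gave all genes 1 dispersion of 0.014 and changed only genes with a mean of at least 50 reads. It held no library that stood apart and no 2 libraries nearly alike, as the real data do. Recovery and false calls on the real data may therefore be worse. Alternatives covered the tool, scaling, low-value filter, pseudocount, fold threshold, a replicate block and each library left out. Figures were drawn with matplotlib 3.10.9.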

Results

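Gene expression was measured by RNA sequencing in mouse cultures that the labels describe as female germline stem cells, mitotic germ cells obtained from the ovary and grown in culture. Cultures received C89, a compound known here only by its code name, or the solvent DMSO, and RNA was taken at 8 h. Each group had 3 libraries. The recovered reads assigned to genes numbered 17826569 to 21763459 per DMSO library and 7772060 to 17938295 per C89 library. Values below are normalized read counts, and log2 fold changes are on the log2(value + 1) scale, C89 over DMSO. Plain fold values between the groups are ratios of group means, or of a group mean to a floor. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The second and the third C89 libraries were nearly alike: counts of 0.6% of genes differed beyond sampling noise between them, against 23 to 44.9% in the other pairs within a group. A chi-square per degree of freedom of 1.6 remained over sampling noise, and they were kept as 2 libraries. If they are not independent, the spread of the C89 group is too small and the p-values are too low. With the 2 summed, 3273 genes were called in place of 4946.

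The comparison asks what C89 did to these cultures within 8 h, and the series title poses it for autophagy and PI3K-AKT signalling. Treated libraries held more RNA of Sqstm1, the autophagy receptor p62, of the lysosomal protease gene Ctsd, of the ferritin gene Fth1 and of Cpa3, which encodes a carboxypeptidase of mast cell granules. Of the fixed gene lists, 39 of 45 ribosomal protein genes, 13 of 20 interferon response genes and 12 of 24 immediate early and ERK genes rose, and 11 of 22 genes of the G2 and M phases of the cell cycle fell. The set calls of these lists were lost with an estimated correlation (adjusted p = 0.689 for each). Transcripts of the core PI3K-AKT-mTOR components moved in both directions. Of 18954 genes tested with limma, 4946 changed at an adjusted p under 0.05, of which 2365 rose and 2581 fell. A log2 fold change of at least 1 in size was reached by 1321 genes, 720 higher and 601 lower. The 2 groups did not overlap in 7753 genes, which is 40.9% of those tested, against 10% by chance. With the libraries scaled by total reads, 1514 genes rose and 4097 fell, so that 27% of the calls were higher in place of 47.8%; that scaling moved the median of genes with a mean of at least 50 from -0.02 to -0.17. The count was 2303 without the second DMSO library, 2911 without the second C89 library, 2612 without the third C89 library, and 1510 with the third DMSO library as the single control.

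Among the rises with the lowest p, Cep41 (ENSMUSG00000029790), a ciliary protein gene, went from 1758 ± 177 to 6368 ± 387 normalized counts (SD, n = 3 each; log2 fold change 1.86, SE 0.09, limma adjusted p = 1.28e-06). Ddx55, a DEAD-box helicase gene, rose from 1236 ± 318 to 5993 ± 326. The apolipoprotein gene Apoe rose from 134 ± 28.0 to 737 ± 33.1, and Ttll3, a tubulin glycylase gene, rose from 54.6 ± 2.51 to 362 ± 37.5. Cpa3 rose from 7285 ± 769.5 to 20899 ± 1792 (adjusted p = 7.34e-06). Of the falls, Grin1, an NMDA receptor subunit gene, went from 484 ± 62.0 to 118 ± 9.20 (log2 fold change -2.03, SE 0.14, adjusted p = 7.34e-06). Angpt1, the gene of the vascular growth factor angiopoietin 1, fell from 991 ± 153 to 328 ± 29.6. Uap1l1, Ubald1 and Trim65 fell with log2 fold changes of -1.44, -1.44 and -1.75.

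By size, the rises were led by Tspoap1, at 13.3 ± 7.64 in DMSO and 420.1 ± 224 in C89 libraries (log2 fold change 4.90, SE 0.39, adjusted p = 1.08e-05). Iigp1, an interferon-inducible GTPase gene, rose 10.64-fold from 17.7 ± 8.12 to 189 ± 25.7. Batf2 had no read in DMSO libraries and 10.8 ± 2.25 in C89 libraries, at least 14.4-fold higher against a floor of 3 reads over the DMSO group. Galr2, Car14, Susd2, Dnhd1, Ccdc7b and Rnaset2a also rose, with log2 fold changes of 3.23 to 3.64. Without the third DMSO library Galr2 was at 2.79 and Car14 at 2.93, and Car14 was at 4.29 without the second. Rnaset2a has a near-identical copy, so its value is uncertain. Olfr461 went from 0.753 to 24.5 normalized counts, with 3 reads behind the DMSO value. The falls were led by the fibronectin gene Fn1, at 620.3 ± 587 in DMSO and 13.1 ± 4.86 in C89 libraries (log2 fold change -4.65, SE 0.80, adjusted p = 0.00133). Next were Ctsa, Actn1, Serpinh1, Pdpn, Cd9, Cpe, Selp and Osmr, each at a C89 mean of 0.295 to 2.38, and Pkd2, which had no read in C89 libraries and was at least 19.9-fold lower. In 8 of these 10 falls the third DMSO library lay more than 3 times below the mean of the other DMSO libraries, as the summed fibroblast genes did. The sizes of these falls depend on single libraries. Fn1 had a log2 fold change of -5.97 without the third DMSO library and of -3.72 without the second. Ctsa, Actn1, Serpinh1, Pdpn, Cpe, Pkd2 and Osmr, at -4.39 to -4.04 with all libraries, were at -5.72 to -5.18 without the third DMSO library and at -3.61 to -3.02 without the second. Without the third C89 library Ctsa, Actn1, Pdpn, Cd9 and Cpe were at -5.00 to -4.74, and without the first Pdpn was at -3.45. Without the second DMSO library Fn1 had an adjusted p of 0.0651, and Ctsa, Actn1, Serpinh1, Pdpn, Cpe, Pkd2 and Osmr also missed the threshold, with adjusted p from 0.0768 to 0.17. Serpinh1 missed it also without the second or the third C89 library (adjusted p = 0.0512 and 0.0637), and Osmr without any library but the third DMSO library (0.0549 to 0.17).

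Autophagy genes did not move as a group. Of 36 genes of the autophagy machinery, 3 rose and 7 fell, the same numbers adjusted over the list alone, with a median log2 fold change of -0.06 (camera adjusted p = 0.355). Gabarap, whose product is joined to autophagosome membranes, rose from 3236 ± 413 to 4753 ± 229.8 (log2 fold change 0.56, SE 0.10, adjusted p = 0.00162). Atg7, the enzyme that activates such proteins, rose from 1150 ± 63.9 to 1598 ± 55.1 (adjusted p = 0.0018). Atg9b fell from 717 ± 44.8 to 480.4 ± 11.8 (log2 fold change -0.58, adjusted p = 0.00116). The initiating kinase gene Ulk1 fell from 663 ± 111 to 476 ± 35.9 (adjusted p = 0.0159), a call lost without the second DMSO library (adjusted p = 0.0994), the third DMSO library (0.0643), the first C89 library (0.0637) or the third C89 library (0.0863). Map1lc3b was at 1449 ± 71.0 and 1641 ± 104 (adjusted p = 0.158), Becn1 had a log2 fold change of 0.14 (SE 0.10, adjusted p = 0.333) and Atg5 one of -0.05 (SE 0.12, adjusted p = 0.787). Map1lc3a had few reads, at 6.08 ± 4.57 and 0.720 ± 0.653 (adjusted p = 0.118; 0.0234 without the third DMSO library). Of 14 autophagy receptor genes 1 rose and 1 fell, also adjusted over the list alone. Sqstm1 (ENSMUSG00000015837) rose 2.62-fold, from 17165 ± 3877 to 44979 ± 409 (log2 fold change 1.42, SE 0.14, adjusted p = 4.60e-05). Ncoa4, the receptor for ferritin, fell with a log2 fold change of -0.39 (adjusted p = 0.0085), a call lost without the second DMSO library (adjusted p = 0.0645), the second C89 library (0.0665) or the third C89 library (0.0671), and 2 receptor genes were lower without the first C89 library. Without the second DMSO library 1 gene of the machinery was lower in place of 7, and with scaling by total reads 12 were lower and 3 higher.

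**Figure D1:**
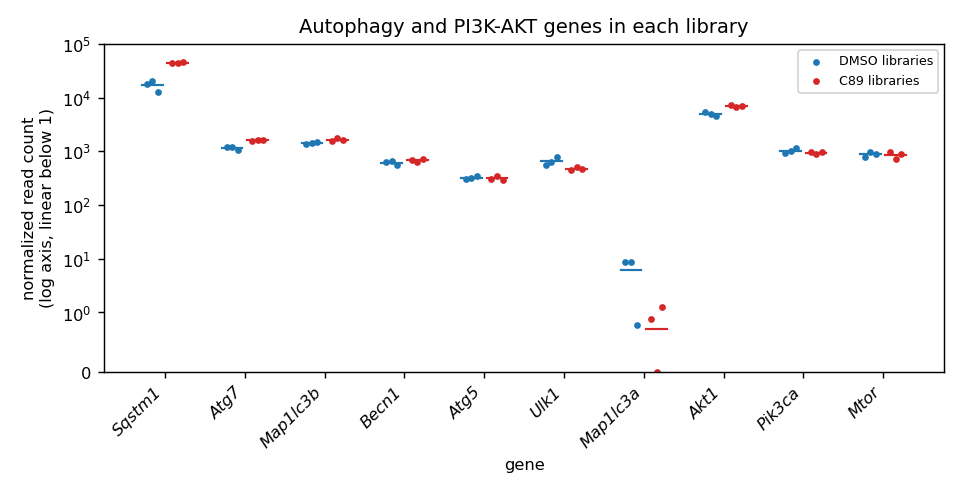
Normalized read counts of 10 autophagy and PI3K-AKT genes (y axis, log above 1) in the 3 DMSO (blue) and 3 C89 (red) libraries, with points for libraries and lines for group means. Sqstm1 had means of 17165 in DMSO and 44979 in C89 libraries, while Becn1, Atg5, Pik3ca and Mtor had adjusted p above 0.05.

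Lysosomal genes went both ways: 11 of 38 rose and 9 fell, or 12 and 11 adjusted over the list alone, with a median of -0.02 and a mean of -0.12, while camera's direction was up (adjusted p = 0.723). Ctsd rose 2.73-fold from 3967 ± 601 to 10845 ± 456 (log2 fold change 1.46, SE 0.11, adjusted p = 9.09e-06). Tfe3, a transcription factor of lysosomal genes, rose 4.57-fold from 251 ± 85.5 to 1146 ± 31.8 (adjusted p = 1.67e-05), and the cathepsin gene Ctsz rose from 2719 ± 301 to 4070 ± 122. The related factor gene Tfeb, chosen after its values were seen, fell from 329 ± 31.0 to 193 ± 7.94 (log2 fold change -0.76, adjusted p = 9.60e-04). Leaving out the second DMSO library left 7 higher and 5 lower lysosomal genes (median 0.09), leaving out the second C89 library left 7 and 6, and leaving out the third C89 library left 6 and 6. With scaling by total reads, 6 rose and 15 fell (median -0.17).

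PI3K-AKT-mTOR genes were split as well: of 36, 6 rose and 12 fell, or 7 and 12 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.325). Pik3cd, a catalytic PI3K subunit gene of blood cells, rose from 16790 ± 2502 to 29072 ± 3101 (log2 fold change 0.80, SE 0.12, adjusted p = 6.81e-04). Akt1 rose from 4981 ± 474 to 6956 ± 283 (log2 fold change 0.49, SE 0.09, adjusted p = 0.00215). The regulatory subunit gene Pik3r3 fell from 71.4 ± 9.30 to 23.1 ± 2.43 (adjusted p = 6.58e-04), and the S6 kinase gene Rps6kb2 fell from 319.7 ± 22.2 to 184 ± 5.51. Pik3ca had a log2 fold change of -0.12 (SE 0.10, adjusted p = 0.427) and Mtor one of -0.07 (SE 0.12, adjusted p = 0.739). Of 20 targets of FOXO factors, which AKT restrains, 4 rose and 7 fell, the same numbers adjusted over the list alone (median -0.29, camera adjusted p = 0.295). Ccng2 and Cdkn1b fell, with log2 fold changes of -1.17 and -0.77, and Tnfsf10 rose, with 1.17. Leaving out the second DMSO library left 2 higher and 3 lower FOXO targets; higher ones numbered 2 without the first C89 library and 1 without the third DMSO, the second C89 or the third C89 library. With scaling by total reads, 2 FOXO targets rose and 7 fell, while 4 PI3K-AKT-mTOR genes rose and 15 fell, with a median of -0.28 for the latter. Transcript levels do not measure AKT phosphorylation or autophagic flux. Leaving out the second DMSO library left 3 higher and 4 lower PI3K-AKT-mTOR genes; lower genes numbered 5 without the third DMSO library, 5 without the second C89 library and 6 without the third C89 library, and higher genes 4 without the third DMSO, the first C89 or the third C89 library.

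Of 35 lists with at least 3 tested members, camera with a preset correlation of 0.01 called 13, of which 11 were higher and 2 lower. None was called with an estimated correlation, where each of the 13 had an adjusted p of 0.689. The self-contained test fry called 4 of the 35 for a shift in 1 direction. For movement in either direction, fry's adjusted p was under 0.05 in all lists but the germ cell (0.189) and fibroblast list (0.115). It was 0.00162 for the autophagy machinery, 3.43e-04 for lysosomal genes and 8.36e-04 for PI3K-AKT-mTOR genes. With the preset correlation camera also called 6 to 15 lists in the other splits of the libraries into 3 and 3, where 0 genes were called. Those splits mixed the groups unevenly, so part of the difference between C89 and DMSO remained in them. Their list calls therefore do not measure false calls. Ribosomal protein genes rose in 39 of 45 cases, or 41 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 2.67e-16; unadjusted p = 0.16 with an estimated correlation). Rpl3 rose from 15902 ± 1118 to 23326 ± 1599, and Rpl37 and Rpl13a rose with log2 fold changes of 0.65 and 0.76. The 39 became 7 without the second DMSO library, 27 without the third DMSO library, 38 without the first DMSO library, 41 without the first C89 library, 17 without the second and 12 without the third, and 0 with the third DMSO library as the single control. With the second and the third C89 library summed, 21 ribosomal protein genes were called higher. The median stayed at 0.39 to 0.52 without any 1 library, and the list stayed called without the second DMSO library (camera adjusted p = 1.30e-12). Ribosome biogenesis genes rose in 10 of 26 cases and none fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 3.56e-04; unadjusted p = 0.281 with an estimated correlation), with Nop58 and Nop14 at log2 fold changes of 0.77 and 0.69. Proteasome genes rose in 11 of 25 cases and none fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 3.90e-04; unadjusted p = 0.339 with an estimated correlation), led by Psma5 at 0.76. Higher genes of ribosome biogenesis numbered 3 without the second DMSO library, where 1 was lower, and 5 without the third DMSO, the second C89 or the third C89 library. Higher proteasome genes numbered 3 without the second DMSO, the second C89 or the third C89 library and 5 without the third DMSO library. With scaling by total reads, 23 ribosomal protein genes rose and none fell (median 0.31), 5 ribosome biogenesis genes rose and 2 fell (median 0.07), and 3 proteasome genes rose and 3 fell (median 0.09).

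Interferon response genes rose in 13 of 20 cases and fell in 2, the same numbers adjusted over the list alone, with a median of 0.92 (camera adjusted p = 1.63e-05; unadjusted p = 0.11 with an estimated correlation). The GTPase gene Gbp2 rose from 92.9 ± 28.0 to 367 ± 108 (log2 fold change 1.98, SE 0.23, adjusted p = 1.35e-04) and Isg15 rose from 219.6 ± 17.1 to 403 ± 25.4. The chemokine gene Cxcl10 fell from 91.3 ± 23.2 to 24.2 ± 2.46 (adjusted p = 3.61e-04). Lower interferon response genes numbered 1 without the second DMSO, the third DMSO, the second C89 or the third C89 library. Immediate early and ERK pathway genes rose in 12 of 24 cases and fell in 2, or 13 and 2 adjusted over the list alone, with a median of 0.55 (camera adjusted p = 1.97e-05; unadjusted p = 0.152 with an estimated correlation). The ERK feedback genes Spry4 and Dusp6 rose with log2 fold changes of 1.47 and 1.09, while the phosphatase gene Dusp4 fell from 123 ± 10.1 to 16.4 ± 4.59 (adjusted p = 1.79e-05). Lower genes of that list numbered 1 without any 1 library but the first C89 library. Of 22 inflammatory NF-kB targets 4 rose and 6 fell, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.295), with 2 higher genes without the third DMSO library or any 1 of the C89 libraries. Il6 rose from 594 ± 257 to 2504 ± 275, Tnf rose from 167 ± 73.2 to 649 ± 16.3, and the NF-kB subunit gene Nfkb2 fell from 1733 ± 166 to 814 ± 15.2 (adjusted p = 1.55e-05).

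ATF4 targets of the amino acid response rose in 10 of 30 cases and fell in 3, or 16 and 4 adjusted over the list alone (median 0.26, camera adjusted p = 6.31e-04; unadjusted p = 0.28 with an estimated correlation). Atf5 rose from 554 ± 34.7 to 1201 ± 25.2, and Nupr1 and the asparaginyl-tRNA synthetase gene Nars rose with log2 fold changes of 0.83 and 0.52. Higher ATF4 targets numbered 6 without the second C89 library, and lower ones 0 without the second DMSO, the second C89 or the third C89 library and 1 without the first C89 library. NRF2 antioxidant genes rose in 8 of 17 cases and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0067, 0.073 without the second DMSO library; unadjusted p = 0.322 with an estimated correlation). Fth1 rose from 46336 ± 10273 to 130414 ± 5449 (log2 fold change 1.52, SE 0.15, adjusted p = 4.23e-05), Gstm1 rose with 0.62, and Osgin1 fell with -1.16. Higher NRF2 genes numbered 4 without the second DMSO library, 5 without the third DMSO library and 3 without the second or the third C89 library. Mitochondrial transcripts rose in 2 of 13 cases, in 1 without the second DMSO library and in 0 without the second or the third C89 library, or in 2 adjusted over the list alone (median 0.14; camera adjusted p = 0.0286, 0.1 without the second DMSO library and 0.0704 without the second C89 library; unadjusted p = 0.304 with an estimated correlation). Over the 12 with a known length the median was 0.15 before and -0.05 after a trend on length and GC content was removed. Their median was -0.01 with scaling by total reads, where no gene rose and the call was lost (adjusted p = 0.204). It was also lost with the replicate block (adjusted p = 0.0798), the second and the third C89 library summed (0.0643) or the third DMSO library as the single control (0.23). With scaling by total reads, 6 ATF4 targets rose and 4 fell, and 3 NRF2 genes rose and 1 fell.

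Genes of the G2 and M phases fell in 11 of 22 cases and none rose, or 12 fell and 2 rose adjusted over the list alone, with a median of -0.24 (camera adjusted p = 9.69e-04; unadjusted p = 0.096 with an estimated correlation). Cenpf, a kinetochore protein gene, fell from 1991 ± 161 to 1148 ± 84.5 (log2 fold change -0.79, SE 0.09, adjusted p = 1.45e-04), and the mitotic kinesin and kinase genes Kif20a and Aurka fell with -0.74 and -0.58. Without the first DMSO library 2 were higher. Among 27 genes of the G1 to S transition 7 rose and 4 fell, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.434), with the cyclin gene Ccnd2 rising from 1109 ± 439.8 to 2719 ± 509. Higher G1 to S genes numbered 1 without the second DMSO library and 4 without the third DMSO, the second C89 or the third C89 library; lower ones numbered 1 or 2 without any 1 library but the second DMSO library. With scaling by total reads, 6 rose and 8 fell. Of 21 p53 targets 9 rose and 3 fell, or 11 and 5 adjusted over the list alone. Their median was 0.25 and their mean -0.25, and camera called them higher (adjusted p = 0.0286; unadjusted p = 0.0917 with an estimated correlation). That call was lost without the second DMSO library (adjusted p = 0.0743), the second C89 library (0.0704) or the third C89 library (0.0653), and with the second and the third C89 library summed (0.0803). Higher p53 targets numbered 5 without the second DMSO library, and lower ones 0 without that library or the third C89 library and 1 without the first DMSO, the first C89 or the second C89 library. The cell cycle inhibitor gene Cdkn1a rose 3.04-fold from 2815 ± 555 to 8570 ± 221 (adjusted p = 9.33e-06), and Pmaip1 and Aen rose with log2 fold changes of 0.90 and 0.75.

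**Figure D2:**
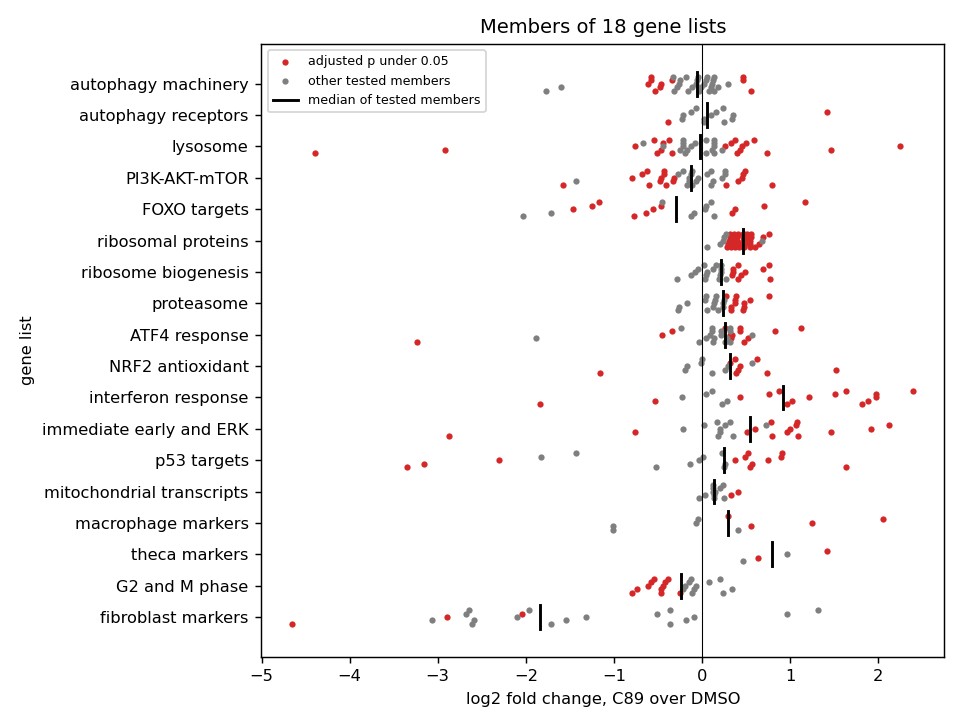
Log2 fold change, C89 over DMSO (x axis), of the tested members of 18 gene lists (y axis), with called genes in red, other tested genes in grey and the list median as a black bar. Medians ran from -1.84 in fibroblast markers to 0.92 in interferon response genes, with -0.06 in the autophagy machinery and -0.13 in the PI3K-AKT-mTOR list.

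Markers of cell types were compared with the label of the cultures. Of 24 germ cell genes, Kit and Piwil2 had a mean above 100 normalized counts. Kit, the stem cell factor receptor gene that blood cells also use, was at 30384 ± 4542 and 42170 ± 6406 (adjusted p = 0.02; 0.0561 to 0.105 without any 1 of the 6 libraries). Dazl had no read in any library, which with 3 reads over each group allows up to 0.75 normalized counts in DMSO and 1.25 in C89 libraries, for counting error only. Ddx4 had 15 reads and Pou5f1 had 4 reads over the 6 libraries. The germ cell list had 1 higher and 2 lower of 10 tested genes, also adjusted over the list alone (camera adjusted p = 0.481). Its lower genes were Zbtb16 and Piwil4, both calls lost without the second DMSO library (adjusted p = 0.142 and 0.141) or the second C89 library (0.0769 and 0.105). Zbtb16 missed the threshold also without the third DMSO library (adjusted p = 0.0679), and Piwil4 without the first DMSO library (0.0645) or the third C89 library (0.111). Ifitm3 was at 43.5 ± 37.5 and 14.5 ± 2.00 (adjusted p = 0.726; 0.00501 without the third DMSO library). Genes of meiosis and the oocyte summed to 63.0 to 100.3 normalized counts per library, and pluripotency genes to 0.886 to 12.7.

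Of 12 macrophage markers, 4 of 9 tested rose, also adjusted over the list alone (camera adjusted p = 0.0197, 0.0575 without the first DMSO library; unadjusted p = 0.209 with an estimated correlation). The adaptor gene Tyrobp rose from 145 ± 30.8 to 596 ± 61.0 (log2 fold change 2.05, adjusted p = 9.33e-06), Adgre1 rose from 917 ± 117 to 2173 ± 138, and Fcer1g rose with 0.56. Of 4 tested theca and steroidogenic genes 2 rose, also adjusted over the list alone (median 0.80, or 1.03 with Hsd3b1 at its bound; camera adjusted p = 0.0258; unadjusted p = 0.0548 with an estimated correlation). Star rose from 77.8 ± 9.62 to 209 ± 15.0 and Cyp11a1 from 4863 ± 668 to 7515 ± 398. Of 5 tested endothelial genes 1 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.517). Their median of 0.06 was -0.22 without the third DMSO library, -0.36, 0.58 and -0.12 without the first, the second and the third C89 library, and 0.20 without the first or the second DMSO library. Vwf rose from 25.2 ± 12.4 to 210.0 ± 44.8, and Egfl7 had a log2 fold change of -0.38 (adjusted p = 0.137).

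Fibroblast genes had a median log2 fold change of -1.84, or -2.68 without the third and -1.20 without the second DMSO library, with 3 of 20 tested genes lower and none higher, or 2 lower adjusted over the list alone (camera adjusted p = 0.0124; unadjusted p = 0.374 with an estimated correlation). Fn1, Pdgfra and Col1a2 fell, with log2 fold changes of -4.65, -2.04 and -2.90, and Col1a1 was at 53.6 ± 45.8 and 10.6 ± 9.60 (adjusted p = 0.0774; 0.0164 without the third DMSO library). Fn1 and Col1a2 were at -5.97 and -4.20 without the third DMSO library and at -3.72 and -1.94 without the second, and Col1a2 was at -2.23 without the first and -3.52 without the third C89 library. Col1a2 had an adjusted p of 0.0856 to 0.327 without the first or second DMSO library or any 1 of the C89 libraries. The 22 fibroblast genes summed to 1570, 2827 and 237 normalized counts in the 3 DMSO libraries and to 185, 193 and 280 in the C89 libraries. Without the third DMSO library 12 genes were lower, without the second 1, and without the first 2, as without any 1 of the C89 libraries. The camera call was lost without the first (adjusted p = 0.119) or second DMSO library (0.158), with scaling by total reads (0.101) or with the third DMSO library as the single control (0.621). The second DMSO library, on which many of the counts above depend, stood apart in markers of other blood cells. B cell genes summed to 414 in it and to 5.10 to 18.3 in the others, T cell genes to 386 and to 153 to 182, and neutrophil genes to 70.1 and to 0.667 to 10.2. Over all tested genes the third DMSO library stood apart, at -82.3 on the second principal component against 3.0 to 38.5 in the others. Without the second DMSO library, the first and the third remain, which differed in 44.9% of genes, the most within a group. The calls lost without the second DMSO library therefore need not come from its blood cell markers.

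**Figure D3:**
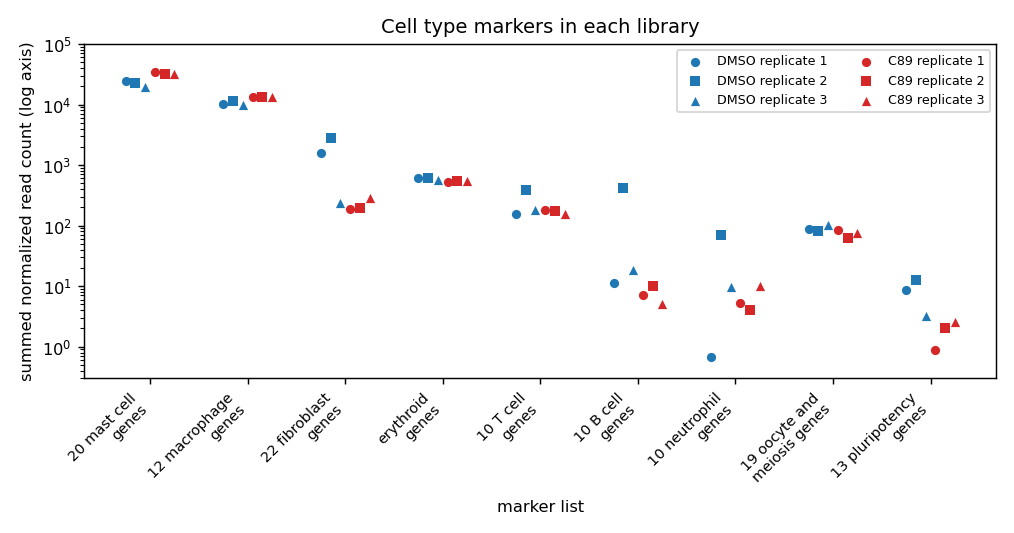
Summed normalized read counts (y axis, log scale) of 9 marker lists (x axis) in each of the 6 libraries, with DMSO in blue, C89 in red and a symbol for each replicate number. Fibroblast genes were at 1570 and 2827 in the first and second DMSO library and at 237 in the third, beside 185 to 280 in C89 libraries.

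The authors' deposited table called 4449 genes at an adjusted p under 0.05, of which 2166 were higher and 2283 lower. Of these, 4294 were called here too, all in the same direction, 155 were called in the authors' deposited table alone and 652 here alone. Of the 10 largest falls here, Ctsa, Serpinh1, Pdpn and Cpe were not called there (adjusted p of 0.0948, 0.109, 0.0524 and 0.153), while Fn1, Actn1, Cd9, Selp, Pkd2 and Osmr were. Fn1 had a log2 fold change of -0.93 there against -4.65 here. Tspoap1, the largest rise here, had 2.37 there without an adjusted p. Over genes called in both, the slope of the authors' log2 fold changes on those here was 0.66. The authors' log2 fold changes ran from -2.51 to 2.82. For genes they called, the median ratio to DESeq2's fold changes from the recovered reads was 0.95. Theirs may have been shrunken, that is, pulled toward no change, so sizes there and here are unlike measures. Across the 15242 genes with an adjusted p in that table, its log2 fold changes had a Pearson r of 0.876 with those computed here; genes are not independent replicates.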

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

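Alternatives that sum the alike C89 libraries, use 1 DMSO library, or rescale by TMM or total reads were chosen after the data were seen. The count of 4946 genes stayed within 1.5 times under edgeR, DESeq2, voom, other scalings, filters, pseudocount and thinning (4036 to 5611). It was 1321 with a log2 fold change of at least 1, 3273 with the second and the third C89 library summed, 1510 with the third DMSO library as the single control, whose spread is then assumed to equal that of the C89 group, and 2303 to 4711 with each library left out. Smaller counts with fewer libraries follow in part from fewer samples. The 13 lists became 0 with an estimated correlation, 4 by fry for a shift in 1 direction and 9 to 14 with each library left out. The replicate numbers did not pair the libraries: deviations of same-numbered libraries had r of -0.24, -0.19 and 0.02, and not every library correlated best with its own number. The replicate block gave 4092 genes and 12 lists. Of 126 named genes called, 123 kept their call with DESeq2, 126 with TMM, 121 with total reads, 115 with the summed libraries, 92 without the second DMSO library and 65 with the single DMSO library; none of these called genes changed sign there. With the single DMSO library the fibroblast list turned upward (adjusted p = 0.621), and log2 fold changes turned to -0.00 for Klf4, 0.31 for Fst, 0.60 for Msln, 0.61 for Wt1, 2.57 for Ifitm3 and 0.07 for Col1a1. Becn1 turned to -0.01 with total reads and Mtor to 0.00 with the summed libraries. With a library left out, Gdf9 ranged from -0.71 to 0.07, Hsd3b1 from 0 to 1.44, Mtor from -0.16 to 0.06, Ddx4 from -0.56 to 0.86 and Ifitm3 from -2.07 to 0.36. The cause was not tested. DESeq2's size factors were not run as a separate alternative for lists and named genes, because the deposited values already use them. Depth limits genes of few reads, such as Ddx4, Klf4 and Hsd3b1.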

Other observations

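The tests on fibroblast genes and on a small share of blood cells, and the added blood cell lists, were chosen after the results were seen; the ribosomal, sex gene and regrouping tests were set before theirs. Cytokine genes outside the fixed lists were also chosen after their values were seen. Il4 rose from 407 ± 46.1 to 1094 ± 49.9 normalized counts (limma adjusted p = 9.09e-06) and Il13 rose from 109 ± 30.1 to 565 ± 17.0 (adjusted p = 9.33e-06). Hdc, the histamine-forming enzyme gene, rose from 80.7 ± 35.9 to 349 ± 94.4, and Tph1, of serotonin synthesis, rose from 4878 ± 1237 to 13582 ± 75.2. Of 15 circadian genes 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.362), with the clock output gene Dbp falling from 433 ± 53.5 to 113 ± 21.6. Of 12 heat shock genes 1 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.238), and the chaperone gene Dnajb1 fell with a log2 fold change of -0.62. Of 14 TGF-beta and BMP targets 4 rose and 3 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.956), with Id2 rising with 1.35. These small counts rest on single libraries, and no heat shock gene was higher without the second DMSO, the third DMSO, the second C89 or the third C89 library, while 2 were higher without the first DMSO library. Without the second DMSO library 1 circadian gene, 2 heat shock genes and 0 TGF-beta and BMP targets were lower, and 2 TGF-beta and BMP targets were higher. Lower circadian genes numbered 5 without the third DMSO library and 1 without the third C89 library. Higher TGF-beta and BMP targets numbered 2 without the third DMSO or the third C89 library, and 1 was lower without the first DMSO library.

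Few germ cell reads stood beside many reads of Kit, Gata2 and Cpa3. Germ cells with a small share of blood cells are argued against, since 2 of 24 germ cell genes had a mean above 100, and 1 of those, Kit, is also a blood cell gene. A hypothesis is that cells of the mast cell lineage gave most of the RNA: 10 of 20 mast cell genes had a mean above 100, exactly the number set beforehand, with Tph1 at 9230, Ndst2 at 5630, Srgn at 4956 and Il1rl1 at 3510, against 1 gene each of the T cell and erythroid lists and none of the B cell and neutrophil lists. The macrophage list was not part of that rule, and 6 of its 12 genes also had a mean above 100. Genes shared by other blood cells were high too, with Ptprc at 5297 and Itga2b at 4107. Of the mast cell protease genes in the list, Tpsb2 had 2 reads and Mcpt4 had 1 read. Cma1 had 220 reads, Mcpt2 had 198, Tpsab1 had 23 and Mcpt1 had 11. Cpa3, which was seen before the list was made, had a mean of 14092. Since macrophage genes and genes shared by other blood cells were high too, the counts do not single out mast cells among related blood cells. Mature mast cells are harder to fit to Ms4a2 without a read and Fcer1a with 1 read, and a mislabelled or mixed culture stays open. Whether the cells were from a female could not be settled, since Y-linked genes reached 11.2 normalized counts in the second DMSO library and 0.667 or less in the others, while Xist had 1 read in all. The second DMSO library is also the 1 that stood apart in B cell, T cell and neutrophil genes.

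Of 20 tested fibroblast genes 3 were called lower in C89 libraries and none higher, the list's call was lost with an estimated correlation (adjusted p = 0.689), and the third DMSO library had a sum of 237, below the 280 of the third C89 library. Less carry-over of fibroblasts may account for the lower values: DMSO libraries differed 11.9-fold among themselves, and 17 of 20 tested genes had the same order of the 3 DMSO libraries. Abundant fibroblast genes were uneven in DMSO libraries, with Fn1 at 620.3 and Dcn at 391 but Sparc at 25.8 and Col3a1 at 4.56, which decides neither way. Lower expression within the cells cannot be told apart, because the lowest DMSO sum was 0.85 times the highest C89 sum. Among the 601 genes lower by a log2 fold change of at least 1 in size, 23.3% had the third DMSO library more than 3 times below the mean of the other DMSO libraries, against 9.2% of all tested genes.

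Of 45 ribosomal protein genes 39 were higher in C89 libraries. A trend on transcript length and GC content is argued against as the whole cause, since the median over 44 genes was 0.44 before and 0.36 after its removal (interquartile range 0.14). Length may account for a part. Among genes with a mean of at least 50, those with transcripts up to 1000 bases had a median of 0.25, against -0.09 over 4000 bases. The length used was that of each gene's longest annotated transcript, which may not be the one expressed. Scaling is argued against as well, with a lowest median of 0.31 with total reads. Without the second DMSO library 7 genes were called higher in place of 39, but the median was 0.41 against 0.46, so the lost calls do not speak for that library as the source. Camera with the preset correlation still called the list. At that setting it also called lists in splits that mixed the groups. Those splits mixed them unevenly, so part of the difference between C89 and DMSO remained, and they cannot decide about this call. With an estimated correlation the list was not called (adjusted p = 0.689). What raised these genes stays open, an effect of C89 included.

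The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 4946 genes and the highest other 0, so 1 split reached the real count. For the lists the real split gave 13 and the highest other 15, and 2 splits reached 13. The other splits gave 6 to 15 lists with 0 genes each, so a camera call at the preset correlation does not by itself mark the real split. Each of them mixed the groups unevenly and kept part of the difference between C89 and DMSO, so their list calls do not measure false calls. The split with 15 set the first and second DMSO and first C89 library against the others.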
